A study of Homo sapiens with 12 samples.

How the data were processed

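Gene expression was measured by RNA sequencing in HUDEP-2 cells, an immortalized line of human erythroid progenitors from umbilical cord blood. Per the labels, the cells carried either a scrambled guide RNA (control) or a disruption of MBD2 (knockout). They were collected before and after erythroid differentiation, with 3 libraries in each of 4 groups and 12 libraries in all. Per the labels, total RNA went through a strand-keeping kit that removes ribosomal RNA and globin mRNA. The medium changed with the stage: expansion medium held stem cell factor and dexamethasone, differentiation medium held human serum, insulin, heparin and transferrin, and both held erythropoietin and doxycycline. The labels name 3 days of differentiation in one place and 5 days in another, which the data cannot settle. They state neither whether the 3 replicates of a group were separate cultures nor whether the knockout cells were a clone.

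The deposited table holds raw counts of read pairs for 60483 genes, with no normalization. Per the file headers, the authors counted pairs over exons by gene identifier with featureCounts 1.4.6-p4 in the GENCODE release 22 annotation of build hg38, with no option for strand. The submitters' processing notes give featureCounts 1.2.6 instead and also name Trimmomatic, FastQC, Subread 1.6.2 and edgeR 3.18.1. Symbols and gene types were joined by identifier from GENCODE release 29, which named 56753 genes and left 3730 without a symbol. Total counts per library ran from 7667997 to 14047498.

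Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter was filterByExpr with the 4 groups, which kept 17175 genes, and libraries were scaled with TMM factors. A group-means model over all 12 libraries was fitted with glmQLFit, and contrasts were tested with the two-sided quasi-likelihood F-test. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with a common biological coefficient of variation of 0.089. Log2 fold changes are given with a standard error equal to their size divided by the square root of the F statistic. Expression per group is given as CPM, the scaled counts from the cpm function of edgeR with TMM-scaled library sizes, as mean ± SD over 3 libraries. For a gene with 3 counts or fewer in a group, the ratio of summed counts is given with its exact 95% binomial interval. Where a group held 0 counts, the floor was 3 counts over the group. Intervals cover counting error only, and a floor covers that of the group at 0 alone.

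The comparisons were knockout against control before differentiation, knockout against control after it, after against before in control cells, after against before in knockout cells, and the difference between the knockout effects at the 2 stages (an interaction contrast). A knockout effect here is any difference between knockout and control cells, whatever its source. Knockout effects at the 2 stages share no library. Genes called the same way at both stages were counted against the number expected from the margins with a one-sided Fisher exact test across genes, which are not independent replicates.

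A set of 30 gene lists was fixed before the data were examined and tested with camera in limma 3.58.1. Camera used log2 CPM with a prior count of 2, a preset correlation of 0.01, at least 4 tested members per list and adjustment over the lists within a contrast. The lists were fetal and embryonic globins, adult-stage globins, fetal globin regulators, NuRD subunits, DNA methylation writers and readers, germline and cancer-testis genes, imprinted genes, heme synthesis, iron uptake and handling, red cell membrane and blood groups, late erythroid maturation, stem and progenitor genes, glucocorticoid response, MYC and ribosome biogenesis, DNA replication and S phase, mitosis, p53 targets, integrated stress response, cholesterol synthesis, glycolysis and hypoxia, interferon response, MHC class I and antigen presentation, replication-dependent histones, mitochondrially encoded genes and immediate early genes. Markers of other cell types made up the remaining lists, for megakaryocytes, mast cells and basophils, neutrophils and monocytes, lymphoid cells, and stromal and endothelial cells. Counts of list members cover only those that passed the filter. For markers these were 6 of 20 megakaryocyte, 13 of 18 mast cell, 10 of 25 neutrophil, 4 of 27 lymphoid and 5 of 25 stromal genes. Other lists cut short were germline (7 of 40), imprinted (12 of 22), interferon (18 of 28) and progenitor genes (17 of 25).

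The rule for named genes was also fixed before the data were examined. It took MBD2, the globins, and in each comparison up to 6 genes per direction with the largest changes. Those were called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between the groups. It added up to 4 members with the smallest adjusted p from the lists of globin regulators, NuRD subunits and DNA methylation, and from each list called. For the interaction it took 4 genes per direction. The genes named in the text were picked from that larger set after their values were seen. BCL11A, ZBTB7A, KLF1, MBD3, CHD4, MT-RNR1 and MT-RNR2 fall outside the rule and were chosen after their values were seen.

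The fit was tested on simulated counts with known changes at the depths and dispersions of these libraries. It recovered 97.0% of 4-fold, 67.2% of 2-fold and 59.7% of 1.5-fold changes in the knockout contrast before differentiation. After differentiation the recovery was 89.4%, 65.7% and 47.8%, and for the interaction it was 81.8%, 50.7% and 26.9%. False calls made up 4.73% to 9.39% of calls. A planted list was called in each of the 5 contrasts, with 1 other list called in 1 of them. Genes were drawn independently, so the simulation cannot show how often lists are called falsely where genes vary together. Before differentiation, a division of the real libraries other than knockout against control called up to 13 lists.

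Alternatives covered DESeq2 1.42.0, other scaling factors (RLE, upper-quartile, library sizes only), no filter and a filter of 1 CPM in 3 libraries, and omission of globin and mitochondrial genes. They also covered a fit on only the 2 groups compared, replicate number as a block, each library left out in turn, and a 2-fold threshold. Lists were also tested with an estimated correlation, with fry, with another prior count, without TMM factors, with the block and without each library. Omission of chromosome 18, and of ribosomal, small RNA and mitochondrial genes, was chosen after seeing the data. XIST and Y-linked genes were left out of all values named here, and no published result was used. One gene is withheld and is not reported here.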

Results

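RNA was sequenced from HUDEP-2 cells with a scrambled guide RNA (control) or with MBD2 disrupted (knockout), before and after erythroid differentiation. MBD2 is a protein that binds methylated DNA and joins the NuRD chromatin remodeling complex. Labels placed the cells at early and late basophilic erythroblast stages, and the series was designed to test how loss of MBD2 affects expression in a human erythroid model. Each of the 4 groups held 3 libraries. Control libraries before differentiation held 10438416, 14047498 and 9833846 counts, and knockout libraries held 13671293, 10708414 and 10651451. After differentiation the control libraries held 10433944, 13705360 and 9450884 counts, and the knockout libraries 9693546, 10192009 and 7667997. The replicates were not stated to be separate cultures, so the p-values measure only the spread between these libraries. An exact two-sided permutation test of 3 against 3 cannot go below p = 0.1, so p-values come from the edgeR fit across genes.

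Counts of ribosomal RNA genes, mitochondrial ones included, made up 0.653 ± 0.378% of control and 1.05 ± 0.27% of knockout libraries before differentiation (SD, n = 3). After it they made up 0.807 ± 0.243% and 2.38 ± 0.574%. Mitochondrially encoded genes took 1.31 ± 0.388% and 1.46 ± 0.125% before, and 1.80 ± 0.179% and 2.18 ± 0.539% after. The mitochondrial ribosomal RNA genes are part of both shares. Globin counts left after removal by the kit took 0.314 ± 0.264% and 0.395 ± 0.224% before, and 0.182 ± 0.117% and 0.650 ± 0.539% after. The first component of a principal component analysis held 56.5% of the variance and the second 19.5%.

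MBD2 mRNA (ENSG00000134046.10, build hg38, chromosome 18, 54151601 to 54224788, minus strand) measured 78.7, 77.7 and 75.3 CPM in the control libraries before differentiation. In the knockout libraries it measured 22.7, 19.8 and 24.5 CPM. After differentiation it measured 61.4, 59.1 and 58.2 CPM in control and 16.8, 16.1 and 14.6 CPM in knockout libraries. The log2 fold change of MBD2 was -1.79 ± 0.08 (adjusted p = 1.06e-10) before and -1.91 ± 0.09 (adjusted p = 5.68e-11) after differentiation. MBD2 lies on chromosome 18, whose genes were lower as a set in the knockout libraries. The median log2 change of 146 genes on that chromosome was -0.48 before and -0.42 after differentiation, and medians of the other 22 chromosomes lay between -0.08 and 0.12. Of 265 tested genes on chromosome 18, 149 fell and 5 rose before differentiation, and 115 fell and 13 rose after it.

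**Figure D1:**
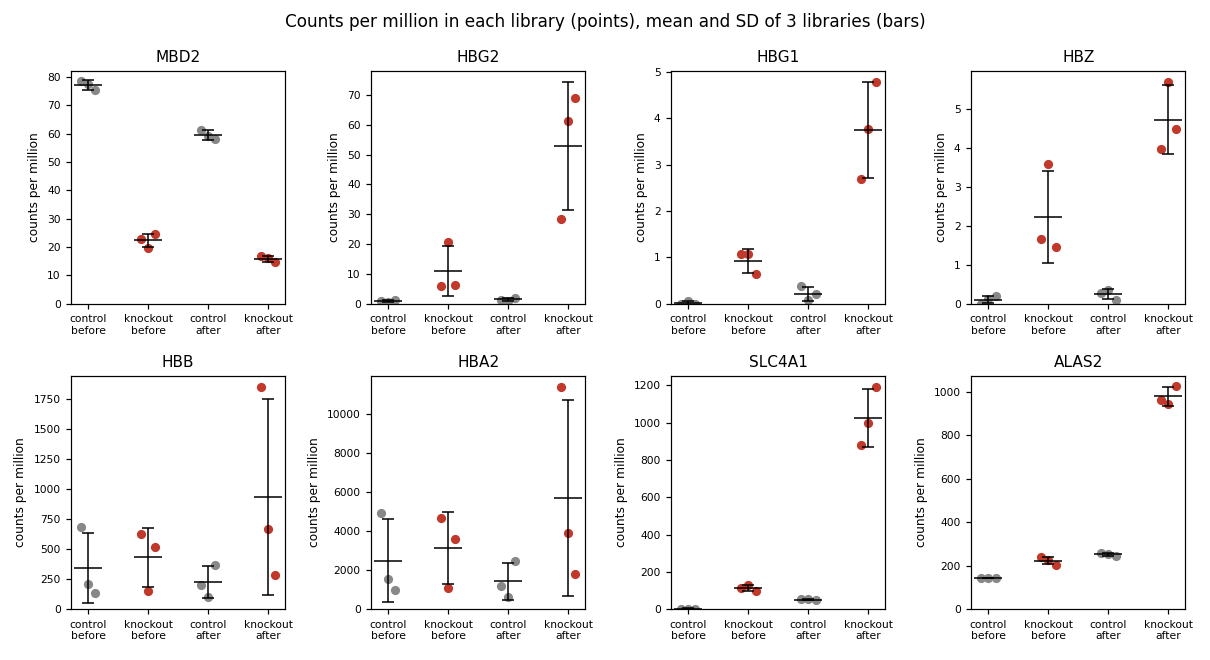
Expression (CPM) of 8 genes in each library (points), with the mean and SD of 3 libraries (bars), in control and knockout cells before and after differentiation. MBD2 was 22.4 ± 2.39 CPM in knockout and 77.2 ± 1.75 CPM in control libraries before differentiation.

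Knockout and control cells were compared before differentiation, in early erythroblasts. The fetal gamma-globin gene HBG2 rose 10.4-fold, from 1.07 ± 0.343 to 11 ± 8.3 CPM (SD, n = 3), with a log2 fold change of 3.37 ± 0.58 (adjusted p = 4.70e-04). Knockout replicate 2 held 20.6 CPM against 6.06 and 6.33 in the others, and without it the log2 change was 2.57. The band 3 anion exchanger SLC4A1, a main protein of the red cell membrane, rose 48.4-fold, from 2.3 ± 0.695 to 113 ± 17.6 CPM. TRIM10, a protein needed in late erythroid maturation, rose 49.9-fold. MS4A2, the beta chain of the mast cell IgE receptor, fell from 69.4 ± 9.26 to 0.994 ± 0.72 CPM, a log2 change of -6.83 without knockout replicate 3. The test called 1558 genes higher and 1400 lower.

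Every tested member of the fetal and embryonic globin list rose before differentiation (5 of 5 measured members rose, 0 fell and 0 did not pass the test, with 5 and 0 adjusted over the list alone; list adjusted p = 9.75e-07). Besides HBG2 (ENSG00000196565.11, chromosome 11, 5248274 to 5645789, minus strand) these were HBG1, the second gamma-globin gene, with 4.60 ± 0.77 (adjusted p = 3.95e-04), and embryonic zeta-globin HBZ with 4.18 ± 0.59 (adjusted p = 7.51e-05). The noncoding genes of the beta-globin cluster were HBBP1 with 3.74 ± 0.46 and BGLT3 with 3.23 ± 0.25. HBG1 held 34 counts over the knockout libraries against 1 in control, a ratio of 33.9 (exact 95% interval 5.69 to 1378), and measured 6.33 without control replicate 2, which held that count. HBG1 shares 580 of its 808 exon bases with HBG2 or another gene, and HBG2 shares 1187 of 2241. The alpha-cluster gene HBZ shares 205 of 755 and HBM 410 of 916, so the levels of these genes depend on how shared reads were counted. HBE1 held 0 to 2 counts per library and was not tested. Of the adult-stage globins, HBM rose with 2.96 ± 0.39 (adjusted p = 3.43e-05). HBB was 0.33 ± 0.64 (adjusted p = 0.793), HBA1 0.27 ± 0.65 (adjusted p = 0.834), HBA2 0.33 ± 0.65 (adjusted p = 0.796), HBD 1.42 ± 0.65 (adjusted p = 0.157) and HBQ1 0.70 ± 0.27 (adjusted p = 0.0886), none of them called. For this list 1 rose, 0 fell and 5 did not pass, with 1 and 0 adjusted over the list alone; list adjusted p = 0.0463, adjusted p = 0.155 with an estimated correlation. Its call was lost without control replicate 3 (adjusted p = 0.15), control replicate 2 (0.0707), knockout replicate 1 (0.117) or knockout replicate 2 after differentiation (0.0525).

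Red cell genes rose together before differentiation. In the list of red cell membrane and blood group genes, 21 of 27 measured members rose, 1 fell and 5 did not pass the test, with 23 and 1 adjusted over the list alone (list adjusted p = 2.06e-15). Examples were SLC4A1 with 5.60 ± 0.18, the glucose transporter SLC2A1 with 1.47 ± 0.08, the water channel AQP1 with 3.30 ± 0.24 and the Dombrock blood group carrier ART4 with 2.13 ± 0.16. Among late erythroid maturation genes, 18 rose, 0 fell and 12 did not pass, with 22 and 1 adjusted over the list alone (list adjusted p = 4.06e-10), including TRIM10 with 5.64 ± 0.15 and the erythroid nuclear protein HEMGN with 1.18 ± 0.11. Heme synthesis genes went the same way (list adjusted p = 4.60e-07, adjusted p = 0.0819 with an estimated correlation), with the first erythroid enzyme ALAS2 at 0.64 ± 0.07 and coproporphyrinogen oxidase CPOX at 0.81 ± 0.07. By gene, 10 members rose, 0 fell and 5 did not pass, with 12 and 0 adjusted over the list alone. Iron genes were called higher as well (list adjusted p = 0.00126), led by the mitochondrial iron importer SLC25A37 at 1.14 ± 0.08. Among its members 7 rose, 1 fell and 12 did not pass, with 9 and 1 adjusted over the list alone.

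Genes of other blood lineages moved in both directions before differentiation. Mast cell and basophil markers fell (list adjusted p = 5.44e-04), with MS4A2 at -6.14 ± 0.24 and the receptor SIGLEC6 at -1.34 ± 0.09. In this list 1 gene rose, 7 fell and 5 did not pass, with 2 and 8 adjusted over the list alone. Neutrophil and monocyte markers rose (list adjusted p = 5.44e-04), among them azurocidin AZU1 at 2.92 ± 0.35, the myeloid transcription factor CEBPA at 1.57 ± 0.21 and neutrophil elastase ELANE at 5.27 ± 0.74. By gene, 6 of the 10 tested members (25 listed) rose, 1 fell and 3 did not pass, with 6 and 1 adjusted over the list alone. ELANE had 54 counts against 1, a ratio of 53.8 (exact 95% interval 9.26 to 2165), and measured 7.00 without control replicate 2. The tested megakaryocyte markers, 6 of 20 listed, rose (list adjusted p = 4.02e-04), with the TGF-beta binding protein LTBP1 at 2.90 ± 0.18. Among these 4 rose, 0 fell and 2 did not pass, with 4 and 0 adjusted over the list alone. Interferon response genes rose (list adjusted p = 1.42e-05), with the exonuclease ISG20 at 2.27 ± 0.23 and the antiviral gene IFIT2 at 1.31 ± 0.15. In this list 8 genes rose, 0 fell and 10 did not pass, with 10 and 0 adjusted over the list alone. Imprinted genes were called higher (list adjusted p = 0.00135), with the cell cycle inhibitor CDKN1C at 1.38 ± 0.18. By gene, 5 members rose, 0 fell and 7 did not pass, with 5 and 0 adjusted over the list alone.

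Stem and progenitor genes fell as a list (list adjusted p = 0.027, adjusted p = 0.161 with an estimated correlation). Among its members 2 rose, 5 fell and 10 did not pass, with 2 and 6 adjusted over the list alone. The adhesion receptor CD44 fell by 0.87 on the log2 scale, the transcription factor ERG had 1 count against 78, a ratio of 0.0128 (exact 95% interval 3.20e-04 to 0.0733; fitted log2 change -5.81, or -7.59 without knockout replicate 2), and the progenitor factor MYB measured -0.35 ± 0.06, while the cytokine receptor FLT3 rose with 0.96 ± 0.15. Without knockout replicate 1 this list had adjusted p = 0.134, and without control replicate 3 it had 0.0539. Ribosome biogenesis genes were called higher (13 rose, 0 fell and 15 did not pass, with 17 and 0 adjusted over the list alone; list adjusted p = 5.59e-06, adjusted p = 0.202 with an estimated correlation), as were glycolysis and hypoxia genes (9 rose, 3 fell and 15 did not pass, with 13 and 3 adjusted over the list alone; list adjusted p = 0.00319, adjusted p = 0.286 with an estimated correlation), where SLC2A1 rose and the pyruvate kinase PKM fell with -0.75 ± 0.10. DNA replication genes were called higher (list adjusted p = 0.0463, adjusted p = 0.294 with an estimated correlation). In this list 6 genes rose, 1 fell and 19 did not pass, with 6 and 1 adjusted over the list alone. The thymidylate synthase TYMS, on chromosome 18, fell with -0.58 ± 0.06. The replication call was lost when any of 7 single libraries was left out, with adjusted p up to 0.0986 without control replicate 2.

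Among regulators of fetal globin, 8 of 32 measured members rose, 3 fell and 21 did not pass the test, with 13 and 6 adjusted over the list alone before differentiation (list adjusted p = 0.0434, adjusted p = 0.286 with an estimated correlation). SOX6, a partner of the gamma-globin repressor BCL11A, rose with 1.78 ± 0.13, and the fetal-type RNA-binding proteins LIN28B and IGF2BP1 rose with 3.34 ± 0.30 and 0.80 ± 0.08. BCL11A itself measured 0.12 ± 0.11 (adjusted p = 0.546), the repressor ZBTB7A 0.21 ± 0.12 (adjusted p = 0.292), and the erythroid factor KLF1 0.28 ± 0.08 (adjusted p = 0.0184). The KLF1 call was lost without control replicate 1 (adjusted p = 0.0905), control replicate 2 (0.0849), knockout replicate 1 (0.0517) or knockout replicate 2 (0.0698). The list itself lost its call without knockout replicate 1 (adjusted p = 0.0903), control replicate 1 (0.0591), control replicate 2 (0.0755) or the genes of chromosome 18 (0.0502). For the DNA methylation list, 5 rose, 1 fell and 11 did not pass, with 5 and 1 adjusted over the list alone (list adjusted p = 0.0306, adjusted p = 0.167 with an estimated correlation). The methylcytosine oxidase TET1 rose with 3.94 ± 0.30 and the maintenance methylation factor UHRF1 with 0.42 ± 0.09. Without knockout replicate 3 that list had adjusted p = 0.0653. NuRD subunits were not called (list adjusted p = 0.711), with a test and mean below 0 (-0.08) and a median of 0.03. By gene, 1 member rose, 1 (MBD2 itself, which also enters the mean) fell and 13 did not pass, with 1 and 1 adjusted over the list alone. Its member MBD3, the alternative subunit to MBD2, measured 0.17 ± 0.10 (adjusted p = 0.286).

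The largest fitted rises before differentiation were those of the unconventional myosin MYO18B (chromosome 22, 25742144 to 26031041), the desmosome protein PKP3 and the zinc finger gene ZNF648. MYO18B had 296 counts against 1, a ratio of 295 (exact 95% interval 52.6 to 11694), and PKP3 had 399 against 2, a ratio of 199 (54.7 to 1648). The fitted log2 change of MYO18B was 7.71, or 9.49 without control replicate 1 and 7.12 without control replicate 2, and that of PKP3 was 7.37, or 9.87 without control replicate 2. ZNF648 rose with 6.76 ± 0.31. NMU, a neuropeptide gene, had 10 counts against 0, at least 3.32-fold higher at the floor of 3 counts, with an exact 95% lower limit of 2.23 once the error of the 10 counts is included. The deepest falls were those of ID4, an inhibitor of basic helix-loop-helix factors, with -7.20 ± 0.29, MS4A2, the retinaldehyde dehydrogenase ALDH1A1 with -5.86 ± 0.32, CYTL1 with -4.04 ± 0.24, KCTD15 with -4.01 ± 0.27 and the aldose reductase AKR1B1 with -3.96 ± 0.30. ALDH1A1 measured -6.69 without knockout replicate 3. The count of higher genes dropped to 1024 without control replicate 1.

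The lists not called before differentiation besides NuRD subunits were mitochondrially encoded genes (adjusted p = 0.0895), integrated stress response (0.144), glucocorticoid response (0.199), stromal markers (0.199), MHC class I (0.317), cholesterol synthesis (0.419), germline genes (0.522), mitosis (0.574), histones (0.624), immediate early genes (0.697), p53 targets (0.697) and lymphoid markers (0.974). Those that passed without knockout replicate 3 were integrated stress response (adjusted p = 7.85e-04) and mitochondrially encoded genes (0.0403). The MHC and mitosis lists had a mean and test above 0 and medians of -0.01 and -0.00. The lymphoid list had a test below 0 with a mean of 0.12. Calls that hold before differentiation with an estimated correlation were red cell membrane, late erythroid, fetal globin, interferon, megakaryocyte, neutrophil, mast cell, iron and imprinted genes, each at adjusted p = 0.021.

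**Figure D2:**
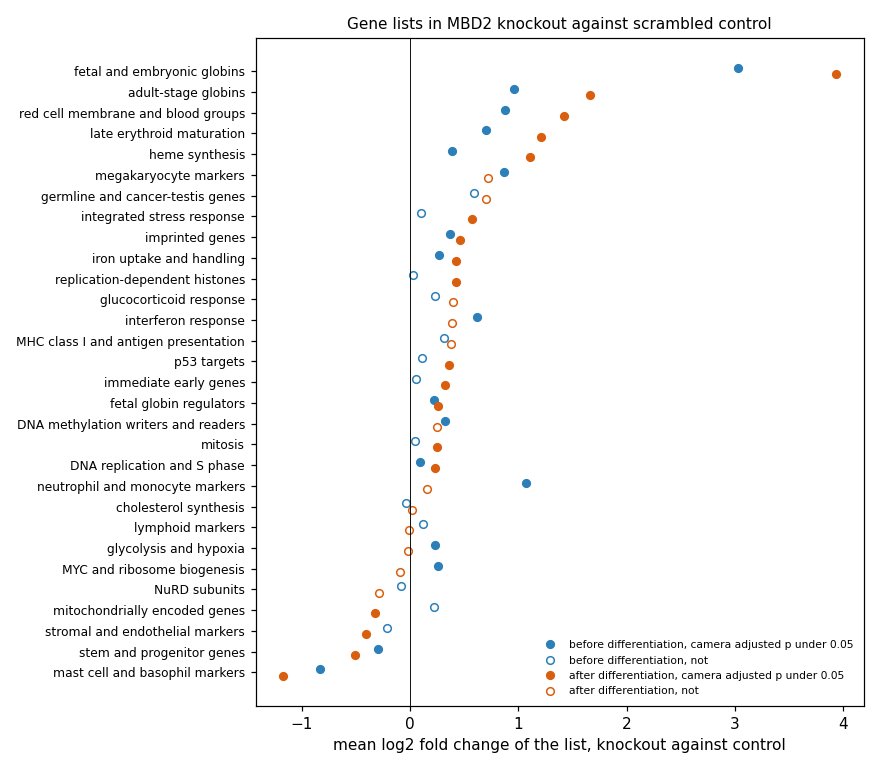
Mean log2 fold change of knockout against control for each of the 30 gene lists, before (blue) and after (orange) differentiation. Filled points mark lists with a camera adjusted p under 0.05, and fetal and embryonic globins lie at 3.03 and 3.93.

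After differentiation the same comparison was made in late basophilic erythroblasts. HBG2 rose 36.9-fold, from 1.46 ± 0.405 to 52.9 ± 21.5 CPM (SD, n = 3), with a log2 fold change of 5.20 ± 0.49 (adjusted p = 2.83e-07). SLC4A1 rose from 51 ± 3.38 to 1024 ± 156 CPM, and the heme enzyme ALAS2 rose 3.88-fold, from 252 ± 5.98 to 977 ± 44 CPM. The mast cell receptor SIGLEC6 and the cytokine receptor chain CSF2RB fell, with -2.42 ± 0.12 and -2.13 ± 0.12. The test called 2882 genes higher and 2805 lower. With library sizes only, 27.6% of the genes called were higher in place of 50.7%, with 1843 called higher and 4826 lower. The median change of all genes moved to -0.17.

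Every tested fetal and embryonic globin gene rose after differentiation (list adjusted p = 1.65e-05). Among its members 5 rose, 0 fell and 0 did not pass, with 5 and 0 adjusted over the list alone. HBG1 measured 4.09 ± 0.44 (adjusted p = 1.30e-06; 4.73 without control replicate 1), HBZ 4.11 ± 0.46 (adjusted p = 2.29e-06), HBBP1 3.96 ± 0.39 and BGLT3 4.05 ± 0.20. Among adult-stage globins, 5 rose, 0 fell and 1 did not pass, with 6 and 0 adjusted over the list alone (list adjusted p = 0.0237, adjusted p = 0.116 with an estimated correlation). HBM rose with 2.68 ± 0.29 and delta-globin HBD with 1.52 ± 0.32 (adjusted p = 0.00138). Beta-globin HBB was 2.07 ± 0.67 (adjusted p = 0.0243) and alpha-globin HBA2 2.00 ± 0.68 (adjusted p = 0.0312), beside the higher globin share of these libraries. Without knockout replicate 1 HBB measured 1.09 (adjusted p = 0.227) and HBA2 1.00 (0.279), while without control replicate 3 HBA2 measured 2.65. Both also lost their call without control replicate 1 (adjusted p = 0.0823 and 0.104), without control replicate 2 (0.0908 and 0.11) and with DESeq2 (0.0713 and 0.0925). HBA1 was not called, with 1.76 ± 0.67 (adjusted p = 0.0538), and passed when 1 of 5 other libraries was left out, with adjusted p down to 0.0182 without knockout replicate 3. HBQ1, with 0.62 ± 0.22 (adjusted p = 0.0388), lost its call without control replicates 1 (0.155) or 3 (0.1), knockout replicates 2 (0.0761) or 3 (0.172), with DESeq2 (0.0745) and with library sizes only (0.116).

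Red cell genes again rose in the knockout. Of the red cell membrane and blood group genes, 25 rose, 1 fell and 1 did not pass, with 26 and 1 adjusted over the list alone (list adjusted p = 9.57e-19), with SLC2A1 at 2.70 ± 0.08, SLC4A1 at 4.33 ± 0.14, ART4 at 3.82 ± 0.15 and the Scianna blood group carrier ERMAP at 1.17 ± 0.06. Late erythroid maturation genes rose (list adjusted p = 3.11e-17), including TRIM10 at 4.76 ± 0.10, the bisphosphoglycerate mutase BPGM at 2.18 ± 0.09 and the transcription factor FOXO3 at 1.79 ± 0.08. In this list 26 genes rose, 1 fell and 3 did not pass, with 27 and 1 adjusted over the list alone. Heme synthesis genes rose (list adjusted p = 1.22e-12), with ALAS2 at 1.96 ± 0.07, CPOX at 1.49 ± 0.07 and uroporphyrinogen synthase UROS at 1.27 ± 0.06. By gene, 14 members rose, 0 fell and 1 did not pass, with 14 and 0 adjusted over the list alone. Iron genes rose (list adjusted p = 2.88e-04), with SLC25A37 at 2.14 ± 0.08. Among its members 10 rose, 1 fell and 9 did not pass, with 10 and 1 adjusted over the list alone.

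Mast cell and basophil markers fell after differentiation (list adjusted p = 1.01e-05), with the ectonucleotidase ENPP3 at -1.02 ± 0.07. In this list 0 genes rose, 9 fell and 4 did not pass, with 0 and 9 adjusted over the list alone. Stem and progenitor genes fell (list adjusted p = 7.17e-04, adjusted p = 0.0606 with an estimated correlation), with the stem cell factor receptor KIT at -0.66 ± 0.06, GATA2 at -1.38 ± 0.15 and MYB at -0.77 ± 0.06. By gene, 1 member rose, 10 fell and 6 did not pass, with 1 and 10 adjusted over the list alone. Replication-dependent histone genes rose (list adjusted p = 7.37e-07, adjusted p = 0.24 with an estimated correlation), with HIST2H2BE at 0.88 ± 0.07. Among its members 18 rose, 1 fell and 3 did not pass, with 18 and 1 adjusted over the list alone. Mitosis genes rose (14 rose, 0 fell and 11 did not pass, with 17 and 0 adjusted over the list alone; list adjusted p = 1.01e-04, adjusted p = 0.219 with an estimated correlation), with the cytokinesis protein ANLN at 0.65 ± 0.06, and DNA replication genes rose (12 rose, 3 fell and 11 did not pass, with 13 and 3 adjusted over the list alone; list adjusted p = 0.00765, adjusted p = 0.189 with an estimated correlation), with the cell cycle factor E2F2 at 1.70 ± 0.10. The replication list had adjusted p = 0.0759 with library sizes only. Integrated stress response genes rose (list adjusted p = 1.02e-05, adjusted p = 0.251 with an estimated correlation), with the pseudokinase TRIB3 at 1.96 ± 0.14 and the stress factor ATF3 at 1.01 ± 0.12. In this list 18 genes rose, 1 fell and 5 did not pass, with 19 and 1 adjusted over the list alone. Imprinted genes rose (list adjusted p = 0.00951, adjusted p = 0.0618 with an estimated correlation), with CDKN1C at 1.53 ± 0.16. By gene, 6 members rose, 1 fell and 5 did not pass, with 7 and 1 adjusted over the list alone. Mitochondrially encoded genes fell as a list (list adjusted p = 0.00185, adjusted p = 0.272 with an estimated correlation), with the complex I gene MT-ND2 at -0.87 ± 0.11. Among its members 2 rose, 11 fell and 2 did not pass, with 2 and 11 adjusted over the list alone. The 2 that rose were the ribosomal RNA genes MT-RNR1 with 1.68 ± 0.47 (adjusted p = 0.0106) and MT-RNR2 with 1.22 ± 0.44 (adjusted p = 0.0424). MT-RNR2 went from 6066 to 14084 CPM, so the share of mitochondrial counts was higher while the list fell. Both are part of the ribosomal RNA gene counts, whose shares were highest in these libraries. MT-RNR1 lost its call without knockout replicate 1 (adjusted p = 0.0764) or control replicate 1 (0.0534). MT-RNR2 lost it without any of 5 single libraries, up to adjusted p = 0.217 without knockout replicate 1, with DESeq2 (0.16) and with library sizes only (0.0624).

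Immediate early genes rose (list adjusted p = 0.0249, adjusted p = 0.272 with an estimated correlation), with the TGF-beta induced factor KLF10 at 0.70 ± 0.09, and the call was lost without knockout replicate 3 (adjusted p = 0.0781). In this list 5 genes rose, 0 fell and 10 did not pass, with 5 and 0 adjusted over the list alone. The p53 targets rose (list adjusted p = 0.0409, adjusted p = 0.234 with an estimated correlation), with the stress cytokine GDF15 at 2.31 ± 0.13. By gene, 7 members rose, 1 fell and 13 did not pass, with 7 and 1 adjusted over the list alone. The p53 call was lost without knockout replicate 3 (0.092), knockout replicate 2 (0.0519), control replicate 1 (0.0554) or control replicate 3 (0.0502), and with library sizes only (0.0689). Stromal and endothelial markers fell (list adjusted p = 0.0425, adjusted p = 0.189 with an estimated correlation), with the intermediate filament VIM at -1.67 ± 0.10. Among its 5 tested members (25 listed) 1 rose, 3 fell and 1 did not pass, with 1 and 3 adjusted over the list alone. That call was lost without control replicate 3 (0.0502), control replicates 1 or 3 before differentiation (0.0586 and 0.0553) or knockout replicate 1 (0.0578), and with library sizes only (0.0728).

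Of the fetal globin regulators, 14 rose, 7 fell and 11 did not pass, with 17 and 7 adjusted over the list alone after differentiation (list adjusted p = 0.0339, adjusted p = 0.234 with an estimated correlation). SOX6 rose with 2.41 ± 0.10, the erythroid factor TAL1 with 0.86 ± 0.06, the heme-regulated kinase EIF2AK1 with 0.82 ± 0.08, BCL11A with 0.62 ± 0.11 (adjusted p = 2.18e-04) and KLF1 with 0.48 ± 0.08 (adjusted p = 1.16e-04). ZBTB7A measured 0.15 ± 0.12 (adjusted p = 0.361). The list's call was lost without knockout replicate 3 (adjusted p = 0.0569) or control replicate 3 (0.0529), and with library sizes only (0.0728). NuRD subunits were not called as a list (list adjusted p = 0.0818), but passed without knockout replicate 3 (0.0413) and with library sizes only (0.0375). In this list 0 genes rose, 6 fell and 9 did not pass, with 0 and 6 adjusted over the list alone. Besides MBD2, the subunit MTA3 fell with -1.40 ± 0.19 (adjusted p = 2.44e-05), while MBD3 measured 0.19 ± 0.11 (adjusted p = 0.192). The remodeler CHD4 measured -0.19 ± 0.06 (adjusted p = 0.0284), a call lost without any of 5 single libraries, up to adjusted p = 0.106 without knockout replicate 1. DNA methylation genes were not called (list adjusted p = 0.147), with TET1 at 3.17 ± 0.32, TET3 at 0.90 ± 0.08 and MBD1, on chromosome 18, at -0.42 ± 0.08. By gene, 6 members rose, 2 fell and 9 did not pass, with 6 and 2 adjusted over the list alone.

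The largest rises after differentiation were MYO18B with 6.94 ± 0.19, HBG2, the corepressor RUNX1T1 with 4.86 ± 0.25, TRIM10, SLC4A1 and the membrane receptor PAQR9 with 4.19 ± 0.18. The deepest falls were ALDH1A1 with -5.36 ± 0.33, ID4 with -5.25 ± 0.33, the sodium channel SCN2A with -4.59 ± 0.20, the cilia-associated gene CFAP161 with -3.77 ± 0.15, FAM198B with -3.75 ± 0.42 and lipoprotein lipase LPL with -3.71 ± 0.36. ALDH1A1 measured -6.07 without knockout replicate 2. Lists not called were germline genes (adjusted p = 0.0544), megakaryocyte markers (0.0609), glucocorticoid response (0.0847), interferon response (0.0976), ribosome biogenesis (0.115), glycolysis (0.299), neutrophil markers (0.526), cholesterol synthesis (0.667), MHC class I (0.719) and lymphoid markers (0.894). The MHC list had a mean of 0.37 and a median of -0.12. Germline genes passed without knockout replicate 2 (adjusted p = 0.0312), control replicate 1 (0.0475) or control replicates 1 or 2 before differentiation (0.044 and 0.038). Germline genes (0.0266), megakaryocyte markers (0.0318), glucocorticoid response (0.0488) and ribosome biogenesis (0.039) passed with library sizes only. Calls that hold after differentiation with an estimated correlation were red cell, late erythroid, mast cell, iron, heme and fetal globin genes, with adjusted p from 0.00967 to 0.0322.

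**Figure D3:**
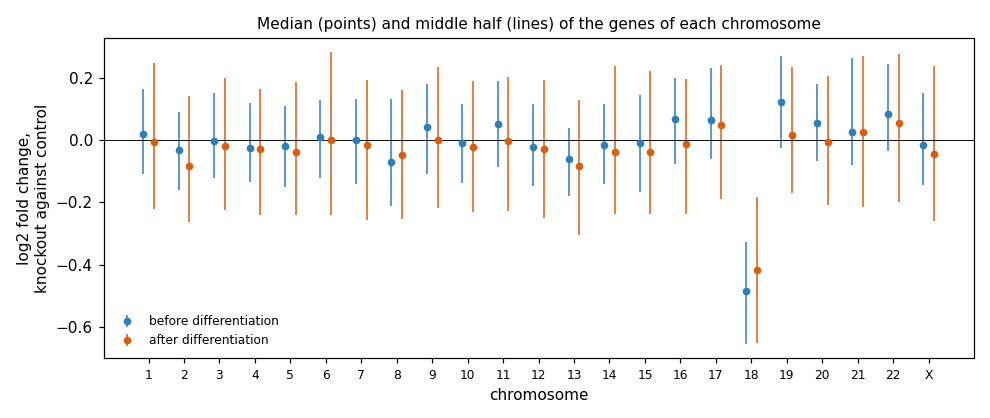
Median log2 fold change of knockout against control for the genes of each chromosome with a mean log2 CPM above 3, with lines over the middle 50% of genes, before (blue) and after (orange) differentiation. Chromosome 18 lies at -0.48 and -0.42.

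Knockout effects were compared across stages to ask which were shared. Of the genes called higher, 922 were higher at both stages against 261 expected, and 875 were lower at both against 229 expected (Fisher exact test across genes, log10 p of -356 and -374). They included HBG2, HBZ, SLC4A1, TRIM10 and SOX6 among the higher genes and MBD2, ID4, ALDH1A1 and SIGLEC6 among the lower. A further 111 genes were called in opposite directions. Across the 17175 genes, which are not independent replicates, Pearson's r was 0.63 and Spearman's rho 0.42. The interaction was called for 2227 genes, of which 2147 were called in a knockout comparison, 1802 with the larger effect after differentiation and 345 before it.

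Effects on red cell genes differed between stages. Heme synthesis genes had a larger knockout effect after differentiation (list adjusted p = 7.22e-11, adjusted p = 0.0647 with an estimated correlation), with ALAS2 differing by 1.32 ± 0.09. Among its members 13 differed upward, 0 downward and 2 did not pass, with 13 and 1 adjusted over the list alone. The late erythroid list (15 differed upward, 1 downward and 14 did not pass, with 20 and 1 adjusted over the list alone; list adjusted p = 2.01e-10, adjusted p = 0.0647 with an estimated correlation) and the red cell membrane list (16 differed upward, 1 downward and 10 did not pass, with 19 and 2 adjusted over the list alone; list adjusted p = 6.22e-10, adjusted p = 0.0647 with an estimated correlation) went the same way. Under the fixed rule, the largest differences upward were those of MS4A2, complement C5 with 3.52 ± 0.52 (adjusted p = 2.74e-04), tensin TNS1 with 3.04 ± 0.27 (adjusted p = 2.42e-06) and TCP11L2 with 2.67 ± 0.16 (adjusted p = 6.25e-08). Those downward were TRIM67 with -3.61 ± 0.24 (adjusted p = 1.32e-07), PKP3 and ZNF648 with -3.02 ± 0.58 (adjusted p = 0.00245). The MS4A2 difference of 4.08 ± 1.04 (adjusted p = 0.0151) was lost without knockout replicate 3 after differentiation (2.83, adjusted p = 0.293) and was 4.77 without knockout replicate 3 before it. NMU had 0 control counts before differentiation, so its fitted difference of -4.29 ± 1.12 (adjusted p = 0.0194) depends on the prior count and is no bound. Its call was lost without control replicate 2 before differentiation (0.0636). The PKP3 difference of -3.22 ± 0.90 (adjusted p = 0.0257) was lost without control replicate 2 after differentiation (0.148) or control replicates 1 or 3 before it (0.0695 and 0.0634), and was -5.71 without control replicate 2 before it. No globin's interaction was called, and that of HBG2 had adjusted p = 0.233. None of the 15 lists called for the interaction held with an estimated correlation. Scaled by library sizes only, 23.1% of the genes called for the interaction differed upward in place of 48.5%, with the median of all genes at -0.15.

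Differentiation of control cells showed the normal course of the line under the change of medium. SLC4A1 rose 21.8-fold, from 2.3 ± 0.695 to 51 ± 3.38 CPM (SD, n = 3). The linker histone H1F0, linked to exit from proliferation, rose with 6.70 ± 0.19 (adjusted p = 1.42e-13), and PHGDH, the first enzyme of serine synthesis, with 4.75 ± 0.21 (adjusted p = 2.46e-11). MS4A2 fell with -5.83 ± 0.23 (adjusted p = 9.36e-12) and the lymphoid factor IKZF2 with -3.45 ± 0.13. The test called 3697 genes higher and 3832 lower.

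Integrated stress response genes rose in control cells (list adjusted p = 1.46e-10, adjusted p = 0.174 with an estimated correlation), with ATF3 at 3.47 ± 0.17 and CEBPB at 1.99 ± 0.11. In this list 20 genes rose, 0 fell and 4 did not pass, with 20 and 0 adjusted over the list alone. Immediate early genes rose (list adjusted p = 4.72e-08, adjusted p = 0.147 with an estimated correlation), with JUND at 1.35 ± 0.10. By gene, 13 members rose, 0 fell and 2 did not pass, with 13 and 0 adjusted over the list alone. Late erythroid genes (21 rose, 2 fell and 7 did not pass, with 21 and 2 adjusted over the list alone; list adjusted p = 5.13e-06, adjusted p = 0.154 with an estimated correlation) and red cell membrane genes (18 rose, 3 fell and 6 did not pass, with 20 and 3 adjusted over the list alone; list adjusted p = 9.87e-06, adjusted p = 0.154 with an estimated correlation) rose, with glycophorin GYPB at 1.64 ± 0.10. Mitochondrially encoded genes rose (list adjusted p = 2.77e-05, adjusted p = 0.262 with an estimated correlation), with MT-ND2 at 1.63 ± 0.12. Among its members 11 rose, 0 fell and 4 did not pass, with 11 and 0 adjusted over the list alone. Fetal globin regulators rose as a list (list adjusted p = 0.00542, adjusted p = 0.171 with an estimated correlation), with the corepressor RCOR1 at 1.33 ± 0.07, SOX6 at 2.16 ± 0.12 and the topoisomerase TOP2B at -0.76 ± 0.07. In this list 21 genes rose, 6 fell and 5 did not pass, with 21 and 6 adjusted over the list alone. Mast cell markers fell (list adjusted p = 0.00542, adjusted p = 0.147 with an estimated correlation), with the carboxypeptidase CPA3 at -5.65 ± 0.37. By gene, 1 member rose, 8 fell and 4 did not pass, with 1 and 8 adjusted over the list alone. MHC class I genes fell (list adjusted p = 0.0173, adjusted p = 0.154 with an estimated correlation), with the proteasome subunit PSMB9 at -3.39 ± 0.18. Among its members 2 rose, 8 fell and 3 did not pass, with 2 and 8 adjusted over the list alone. NuRD subunits fell (list adjusted p = 0.0412, adjusted p = 0.154 with an estimated correlation), with RBBP7 at -0.39 ± 0.06 and MBD2 at -0.37 ± 0.07. In this list 0 genes rose, 9 fell and 6 did not pass, with 1 and 9 adjusted over the list alone. The NuRD call was lost without control replicate 2 or 3 after differentiation (adjusted p = 0.0522 and 0.0566), control replicate 3 before it (0.0544) or the genes of chromosome 18 (0.0629).

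Of the globins, HBD rose in control cells with 2.91 ± 0.53, HBM with 2.01 ± 0.43, HBQ1 with 1.34 ± 0.26 and BGLT3 with 0.96 ± 0.34 (adjusted p = 0.0296). BGLT3 lost its call without control replicate 2 after differentiation (adjusted p = 0.224), control replicates 2 or 3 before it (0.108 and 0.11), with DESeq2 (0.0684) and with no filter (0.0719). HBG2 was 0.45 ± 0.83 (adjusted p = 0.697) and HBB -0.62 ± 0.65 (adjusted p = 0.475). HBZ was 1.17 ± 0.93 (adjusted p = 0.335), HBBP1 1.09 ± 0.61 (adjusted p = 0.166), HBA1 -0.67 ± 0.66 (adjusted p = 0.446) and HBA2 -0.79 ± 0.66 (adjusted p = 0.357). HBG1 had 7 counts after against 1 before, a ratio of 7.41 (exact 95% interval 0.952 to 334), and passed without control replicate 2 after differentiation (adjusted p = 0.0397). Other large rises were NMU, with 548 counts against 0 and at least 193-fold higher at the floor (exact 95% lower limit 157), the zinc exporter SLC30A1 with 4.54 ± 0.17 and the metallothionein MT1X with 4.34 ± 0.27. Other deep falls were FLT3 with -4.10 ± 0.28, ANKRD33B with -3.65 ± 0.17 and the zinc finger repressor SNAI2 with -3.50 ± 0.18. Of the DNA methylation genes, which were not called as a list (list adjusted p = 0.766), the methyl-binding factor ZBTB38 fell with -1.10 ± 0.14. By gene, 5 members rose, 6 fell and 6 did not pass, with 5 and 6 adjusted over the list alone. The remaining lists were not called either, with adjusted p from 0.0513 for neutrophil markers to 0.897 for germline genes. Neutrophil markers passed when 1 of 6 single libraries was left out, down to adjusted p = 0.0306 without knockout replicate 2 after differentiation. Iron genes passed without knockout replicate 2 before differentiation (0.0455). The p53 list had a test below 0 with a mean of 0.25, the lymphoid list a test above 0 with a mean of -0.09, the stromal list a test below 0 with a median of 0.05, and the histone list a test below 0 with a median of 0.01. None of the 9 calls held with an estimated correlation.

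Differentiation of knockout cells moved more genes, with 4807 called higher and 4756 lower. SLC2A1 rose with 2.10 ± 0.08 (adjusted p = 1.82e-12), ALAS2 with 2.13 ± 0.07 (adjusted p = 3.92e-13), and the heme enzyme FECH, on chromosome 18, with 1.30 ± 0.07. RHEX, a regulator of erythroid expansion, fell with -5.73 ± 0.13 (adjusted p = 6.83e-15), and the glycolytic enzymes LDHA and ENO1 fell with -2.06 ± 0.07 and -1.97 ± 0.07. MBD2 measured -0.49 ± 0.09 (adjusted p = 2.37e-04). With library sizes only, 35.1% of the genes called were higher in place of 50.3%, with 3427 called higher and 6337 lower. The median change of all genes was then -0.16.

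Red cell membrane (25 rose, 1 fell and 1 did not pass, with 25 and 1 adjusted over the list alone; list adjusted p = 8.16e-11), late erythroid (27 rose, 1 fell and 2 did not pass, with 27 and 1 adjusted over the list alone; list adjusted p = 1.49e-10), heme (14 rose, 0 fell and 1 did not pass, with 14 and 0 adjusted over the list alone; list adjusted p = 9.08e-07, adjusted p = 0.117 with an estimated correlation) and iron genes (13 rose, 2 fell and 5 did not pass, with 14 and 2 adjusted over the list alone; list adjusted p = 0.0014) rose in knockout cells, with the iron transporter SLC11A2 at 1.02 ± 0.09. Stress response (23 rose, 0 fell and 1 did not pass, with 23 and 0 adjusted over the list alone; list adjusted p = 6.37e-11, adjusted p = 0.176 with an estimated correlation) and immediate early genes (13 rose, 0 fell and 2 did not pass, with 13 and 0 adjusted over the list alone; list adjusted p = 1.66e-06, adjusted p = 0.0823 with an estimated correlation) rose, with TRIB3 at 3.88 ± 0.16. Histone (15 rose, 2 fell and 5 did not pass, with 15 and 2 adjusted over the list alone; list adjusted p = 0.00357, adjusted p = 0.455 with an estimated correlation) and mitosis genes (16 rose, 2 fell and 7 did not pass, with 16 and 2 adjusted over the list alone; list adjusted p = 0.00928, adjusted p = 0.409 with an estimated correlation) rose, although HIST4H4 fell with -1.32 ± 0.09. Fetal globins rose (5 rose, 0 fell and 0 did not pass, with 5 and 0 adjusted over the list alone; list adjusted p = 0.0364, adjusted p = 0.218 with an estimated correlation), with HBG2 at 2.28 ± 0.36 (3.09 without knockout replicate 2 before differentiation) and BGLT3 at 1.78 ± 0.15, and fetal globin regulators rose (19 rose, 8 fell and 5 did not pass, with 21 and 8 adjusted over the list alone; list adjusted p = 0.0224, adjusted p = 0.218 with an estimated correlation). The fetal globin call was lost without knockout replicate 3 after differentiation (adjusted p = 0.0526), without knockout replicate 1 before it (0.0576) and with a prior count of 0.5 (0.0666).

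Mast cell (1 rose, 11 fell and 1 did not pass, with 1 and 11 adjusted over the list alone; list adjusted p = 2.52e-04) and neutrophil markers (1 rose, 9 fell and 0 did not pass, with 1 and 9 adjusted over the list alone; list adjusted p = 0.00119) fell in knockout cells, with CPA3 at 1 count against 232, a ratio of 0.00623 (exact 95% interval 1.57e-04 to 0.0351; fitted log2 change -6.96, or -9.15 without knockout replicate 2 after differentiation), and lysozyme LYZ at -3.48 ± 0.26. Ribosome biogenesis genes fell (list adjusted p = 3.15e-04, adjusted p = 0.307 with an estimated correlation), with WDR43 at -0.65 ± 0.06 and NOP56 at -0.69 ± 0.06. Among its members 0 rose, 18 fell and 10 did not pass, with 0 and 19 adjusted over the list alone. The ribosomal RNA gene share of knockout libraries after differentiation, mitochondrial genes included, was 2.38%. NuRD subunits (0 rose, 9 fell and 6 did not pass, with 0 and 9 adjusted over the list alone; list adjusted p = 0.00928, adjusted p = 0.0806 with an estimated correlation) and progenitor genes (2 rose, 8 fell and 7 did not pass, with 2 and 9 adjusted over the list alone; list adjusted p = 0.0364, adjusted p = 0.192 with an estimated correlation) fell. Interferon (4 rose, 12 fell and 2 did not pass, with 4 and 12 adjusted over the list alone; list adjusted p = 0.0372, adjusted p = 0.177 with an estimated correlation), glycolysis (8 rose, 14 fell and 5 did not pass, with 8 and 15 adjusted over the list alone; list adjusted p = 0.0387, adjusted p = 0.437 with an estimated correlation) and MHC class I genes (3 rose, 8 fell and 2 did not pass, with 3 and 8 adjusted over the list alone; list adjusted p = 0.0409, adjusted p = 0.176 with an estimated correlation) fell, with BST2 at -1.64 ± 0.10, HLA-E at -1.33 ± 0.09 and PKM at -3.20 ± 0.14. The interferon call was lost when any of 9 single libraries was left out, up to adjusted p = 0.0757 without knockout replicate 3 after differentiation. The glycolysis call was lost without knockout replicate 1 after differentiation (0.0592), and the MHC call without knockout replicate 3 after it (0.0547) or knockout replicate 1 before it (0.0576). The interferon (0.0786), glycolysis (0.0895), MHC (0.0895) and mitosis (0.0787) calls were lost with library sizes only. Red cell, late erythroid, mast cell, iron and neutrophil calls hold with an estimated correlation.

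Other large rises in knockout cells were H1F0 with 4.96 ± 0.11, NMU with 6.16 ± 0.25, C5 with 4.37 ± 0.26, the apolipoprotein APOL6 with 4.22 ± 0.19 and the potassium channel KCNN4 with 4.14 ± 0.11. Deep falls were ZNF114 with -5.59 ± 0.44, STMN3 with -4.76 ± 0.47, the orphan receptor GPR85 with -4.44 ± 0.16 and ARPP21 with -4.42 ± 0.46. Without knockout replicate 1 after differentiation STMN3 measured -6.01, and ARPP21 measured -3.78 without knockout replicate 2 and -5.45 without knockout replicate 3 after differentiation. Lists not called included adult-stage globins (list adjusted p = 0.113), DNA replication (0.17) and DNA methylation genes (0.923). Of the adult-stage globins, 3 rose, 0 fell and 3 did not pass, with 3 and 0 adjusted over the list alone. Adult-stage globins passed with library sizes only (adjusted p = 0.0491). The methylation list had a test above 0 with a mean of -0.07, and the lymphoid list a test above 0 with a mean of -0.22. Of the genes called on differentiation of control cells, 2921 also rose in knockout cells against 1035 expected and 3106 also fell against 1061 expected, with 118 in opposite directions. Across genes, Pearson's r was 0.80 and Spearman's rho 0.76.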

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

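The tests in this part were planned, and the genes shown were picked from the fixed rule's set after their values were seen, except BCL11A, which falls outside the rule. The knockout effect differed between the stages for 2227 genes by the interaction test of edgeR. Each value here is the effect after differentiation minus the effect before it, on the log2 scale, with an adjusted p under 0.05.

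Red cell and heme genes had a larger knockout effect after differentiation. In the heme and iron groups, ALAS2 by 1.32, CPOX by 0.69, FAM210B by 0.67, UROS by 0.96, FECH by 0.70 and SLC25A37 by 1.00 differed upward, and FECH lies on chromosome 18. Among membrane and maturation genes, SLC2A1 by 1.23, ART4 by 1.68, ERMAP by 0.87, SELENBP1 by 0.99, BPGM by 1.33 and FOXO3 by 1.41 differed upward. SLC4A1 and TRIM10 rose at both stages but less after differentiation, with differences of -1.27 and -0.88. No list call in this part held with an estimated correlation, whose adjusted p follows each mean in brackets. The mean difference was 0.73 for heme synthesis (0.0647), 0.54 for red cell membrane (0.0647), 0.51 for late erythroid (0.0647) and 0.16 for iron genes (0.0885).

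The lists of fetal globin regulators (adjusted p = 0.555; 5 differed upward, 3 downward and 24 did not pass), NuRD subunits (0.11; 0 differed upward, 2 downward and 13 did not pass) and DNA methylation genes (0.828; 1 differed upward, 1 downward and 15 did not pass) were not called. Of their members, SOX6 by 0.63, TAL1 by 0.63, EIF2AK1 by 0.65, BCL11A by 0.50 and TET3 by 0.55 differed upward, and IGF2BP1 by -0.45, MYB by -0.42, CDK2AP1 by -0.74 and MTA3 by -1.22 downward. Progenitor and mast cell genes CSF2RB by -1.73, KIT by -0.50, GATA2 by -1.23, SIGLEC6 by -1.08 and ENPP3 by -0.99 differed downward, while CD44, which fell less after differentiation, differed by 0.59, SNAI2 by 2.38 and MS4A2 by 4.08. Means were -0.21 for progenitor genes (0.272), -0.34 for mast cell markers (0.0647) and -0.91 for neutrophil and monocyte markers (0.114), with AZU1 at -2.88. LTBP1 differed by -0.85, ISG20 by 1.05, IFIT2 by -1.35, BST2 by -0.91 and HLA-E by -0.41.

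Of the integrated stress response genes 5 differed upward, 0 downward and 19 did not pass, with TRIB3 by 1.11. Of p53 targets 4 differed upward, 1 downward and 16 did not pass, with GDF15 by 1.00, of immediate early genes 4 differed upward, 0 downward and 11 did not pass, with KLF10 by 0.65, and of mitosis genes 10 differed upward, 0 downward and 15 did not pass, with ANLN by 0.38. E2F2 differed by 1.09, while its DNA replication list was not called (adjusted p = 0.076). Of replication-dependent histones 15 differed upward, 1 downward and 6 did not pass, with HIST2H2BE at 0.60, HIST2H2AC at 0.77 and HIST4H4 at -0.42, and the linker histone H1F0, outside that list, differed by -1.74. Means were 0.39 for histones (0.274), 0.46 for stress response (0.289), 0.27 for immediate early genes (0.289), 0.25 for p53 targets (0.274) and 0.20 for mitosis (0.274), with the adjusted p at an estimated correlation in brackets. The p53 call was lost when any of 6 single libraries was left out, up to adjusted p = 0.148 without knockout replicate 3 after differentiation.

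Of glycolysis and hypoxia genes 1 differed upward, 10 downward and 16 did not pass, with LDHA by -0.66, ENO1 by -0.98 and PKM by -1.19. Of ribosome biogenesis genes 0 differed upward, 11 downward and 17 did not pass, with PES1 by -0.48, WDR43 by -0.38 and NOP56 by -0.40. The share of ribosomal RNA genes, mitochondrial ones included, was highest in the knockout libraries after differentiation. The mitochondrial gene MT-ND2 differed by -0.86. Means were -0.25 for glycolysis (0.274), -0.35 for ribosome biogenesis (0.272) and -0.55 for mitochondrially encoded genes (0.272), again with the adjusted p at an estimated correlation. The calls of progenitor genes (adjusted p = 0.0542), neutrophil markers (0.0501) and p53 targets (0.0651) were lost with library sizes only.

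Among genes with the largest changes, C5 by 3.52, TNS1 by 3.04, TCP11L2 by 2.67 and KCNN4 by 1.01 differed upward. TRIM67 by -3.61, PKP3 by -3.22, ZNF648 by -3.02, CFAP161 by -2.58, RHEX by -2.54, ARPP21 by -2.41, GPR85 by -1.16 and SCN2A by -1.003 differed downward. NMU had 0 control counts before differentiation, so its fitted difference of -4.29 depends on the prior count and is no bound. The differences of PKP3 and MS4A2 rest on few counts in a group, and each of the 3 calls was lost on leaving out 1 library. NMU had adjusted p = 0.0636 without control replicate 2 before differentiation, PKP3 0.148 without control replicate 2 after it, and 0.0695 and 0.0634 without control replicates 1 and 3 before it, while without control replicate 2 before it the difference was -5.71. MS4A2 had 0.293 (difference 2.83) without knockout replicate 3 after differentiation and a difference of 4.77 without knockout replicate 3 before it.

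Other divisions of the libraries were tried for the interaction, 100 of 200 possible, the real one included. For genes, 5 reached the real 2227 (highest other 2886). The 4 others kept the real genotypes after differentiation, so they carried that knockout effect and cannot test chance. The highest count was 77 without that grouping and 0 without the real grouping at either stage. For lists, 10 reached the real 15 (highest other 17), with no such breakdown. Neither test decides on chance.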

How the results depend on the processing

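The omission of chromosome 18 and the omission of ribosomal, mitochondrial and small RNA genes were chosen after seeing the data. No named gene reversed its direction past the threshold with DESeq2, RLE factors, library sizes only, no filter, the block or a library left out. No list did so with an estimated correlation, fry, library sizes only, another prior count, the block, chromosome 18 or a library left out. Counts of called genes stayed within 1.5 times those given, except as follows. With a 2-fold threshold added, which admits fewer genes by construction, 466 genes were higher and 269 lower in knockout cells before differentiation. The counts were 783 and 601 after it, 1027 and 836 on control differentiation, 1787 and 1548 on knockout differentiation, and 489 for the interaction. Scaled by library sizes only, 1843 genes were higher and 4826 lower after differentiation. TMM factors of the knockout libraries after differentiation ran from 0.883 to 0.931, against 1.01 to 1.07 elsewhere. Leaving out 1 library gave 1024 (without control replicate 1 before differentiation) to 1589 genes higher in the knockout before differentiation. The causes of these shifts were not tested.

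With an estimated correlation the lists called dropped to 9, 6, 0, 5 and 0 for the knockout before and after differentiation, control differentiation, knockout differentiation and the interaction. The fry test, which asks only whether a list moves, called 21 on control differentiation. Residuals of libraries with the same replicate number correlated at only -0.02 to 0.24, so pairing by number is neither shown nor excluded. On control differentiation each library correlated best with its own number, and on knockout differentiation none did. The main fit left pairing out. With replicate number as a block, 1869 genes were higher and 1622 lower before differentiation, 3117 and 3020 after it, 3978 and 4052 on control differentiation, and 5043 and 4949 on knockout differentiation. The block gave 2728 interaction genes and 2030 genes shared between stages, and 18, 18, 8, 17 and 14 lists. DESeq2 called 81.9% to 87.9% of the genes that edgeR called in a contrast. Without chromosome 18, 1428 genes were higher and 1299 lower before differentiation, 2876 and 2656 after it. Without ribosomal, mitochondrial and small RNA genes the counts were 1649 and 1410, and 2759 and 3000.

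For the named genes, DESeq2 ended 8 calls and added 0, library sizes only ended 4 and added 0, and no filter ended 3 and added 9. Leaving out libraries ended a named gene's call in 53 of the refits and added one in 8, mostly for HBB, HBA1, HBA2, HBQ1, BGLT3, KLF1, CDK2AP1, CHD3, CHD4, MT-RNR2 and TAGLN. RLE factors changed 0 calls. Counts simulated at the depths, dispersions and 3 replicates of these libraries recovered 1.5-fold changes in 26.9% to 59.7% of cases, and depth was not varied alone.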

Other observations

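The test of chromosome 18 along its length, both tests of globin removal and the test of handling were chosen after the result was seen, and so was the added comparison before differentiation in the test of near-silent genes. Of 3697 genes that rose on control differentiation, 591 rose and 234 fell in the knockout before differentiation, and 1136 rose and 474 fell after it. Of 3832 genes that fell, 297 rose and 704 fell before it, and 421 rose and 1295 fell after it. The others were not called in the knockout. Shared control libraries alone gave a rho across genes of 0.45 before and -0.44 after differentiation in simulations with neither a knockout nor a differentiation effect. Those values give the direction of the effect of sharing, not its size in these counts. The counts before differentiation thus do not show agreement by themselves, and those after it run against the effect of sharing. SLC4A1 and TRIM10 rose in each of these comparisons, and MS4A2 and SIGLEC6 fell in each.

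Small RNA genes took a larger share of counts after differentiation, 13.5 ± 0.578% against 9.61 ± 0.469% in control libraries and 12.2 ± 0.370% against 8.84 ± 0.807% in knockout libraries (SD, n = 3). The 10 most abundant genes took 14.1 ± 0.567% against 10.5 ± 0.656% in control and 16.3 ± 1.83% against 10.7 ± 0.539% in knockout libraries.

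Red cell, heme and late erythroid genes were higher in the knockout at both stages. Handling or RNA quality of the knockout libraries after differentiation could not act on the libraries taken before it. Those earlier libraries therefore cannot test it as a source of the rise after differentiation, and it stays open there. At that later stage the mean of the red cell list was 1.42 higher. The ribosomal RNA gene share was then 2.38 ± 0.574% in knockout and 0.807 ± 0.243% in control libraries. Before differentiation the mean of the red cell list was already 0.88 higher, a rise that handling of the later libraries cannot give. That value does not speak to handling before differentiation, where the ribosomal RNA gene share was 1.05 ± 0.27% in knockout and 0.653 ± 0.378% in control libraries. Knockout cells may stand further along differentiation. Across 17093 genes the knockout change after differentiation and the change on control differentiation had a Spearman rho of 0.22, just above the bound set beforehand. Simulations with neither a knockout nor a differentiation effect gave -0.44, which reflects the control libraries they share. With every change removed, the simulated rho is no baseline for the size of the observed rho. The knockout change before differentiation had a rho of -0.02 with knockout differentiation (-0.43 with no effect) and 0.20 with control differentiation (0.45 with no effect). The covariance of these 3 pairs exceeded its simulated value with no effect by 0.161, 0.0643 and 0.123. A direct effect of MBD2 loss on these genes was not tested and stays open.

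Genes of chromosome 18, which holds MBD2, were lower in the knockout, at 71.6% of control before and 74.9% after differentiation. Matched genes elsewhere with like GC content, length and level had medians no lower than -0.0265, which argues against those features, and the highest knockout library median minus the lowest control median was -0.37 or lower at each stage, which argues against a single library. A lower copy number of chromosome 18 in the knockout cells may account for it, since among 10 Mb stretches with at least 5 genes the median nearest to 0 was -0.31. A last stretch with 2 genes had -0.22 before and -0.36 after differentiation. Across expression levels and noncoding genes the nearest value was -0.23, which leaves that explanation open for noncoding genes. If knockout and control cells differ in more than MBD2, the knockout effects on other chromosomes may not all follow from MBD2 loss. These libraries cannot tell such a difference apart from MBD2 loss, and leaving out chromosome 18 genes does not test it. MBD2 itself, at -1.79 and -1.91, lay far below the rest of the chromosome.

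Globin genes were higher in the knockout, in libraries from a kit that removes globin mRNA. Before differentiation the log2 change of HBG2 less 2 standard errors lay 0.60 above that of HBB plus 2 standard errors. This margin was -0.577 without control replicate 1 and -0.374 without knockout replicate 2, while the difference of 3.04 between the 2 changes stayed above its 2 standard errors (1.73 with all libraries) in each refit if the genes are taken as independent. Within libraries, the log2 ratio of HBG2 to HBB differed by 2.72 with 2 standard errors of 2.68 (exact permutation p = 0.2, where 0.1 is the smallest possible). The lowest knockout value of -6.68 lay below the highest control value of -6.58, so unequal removal stays open for HBG2 at that stage. The same ratio after differentiation differed by 3.27 with 2 standard errors of 2.68 (exact permutation p = 0.1). There the lowest knockout value of -6.02 lay above the highest control value of -6.57. After differentiation unequal removal may account for HBB and HBA2, since the change of HBB was only 0.638 of its largest ratio within a group, which reached 6.57. Across the 12 libraries, deviations of HBB from its group mean correlated at 0.995 with HBA1 and 0.999 with HBA2, and at -0.58 with HBG2 and -0.86 with HBBP1. A biological rise of HBB and HBA2 stays open.

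A separate hypothesis was that loss of MBD2 releases near-silent genes. Each comparison used genes under 1 CPM in a group outside it, so the sets of genes differ. These genes passed the filter mostly through other groups, where they were higher, which can by itself raise each share below. Of 1727 genes picked in control libraries before differentiation, 88.1% of those called in the knockout after differentiation were higher. Of 1715 genes picked in knockout libraries before differentiation, 82.4% of those called on control differentiation were higher, which is 5.70 percentage points less. Of 1407 genes picked in control libraries after differentiation, 75.1% of those called in the knockout before it were higher. Of the 1727 genes picked in control libraries before it, 85.2% of those called on knockout differentiation were higher, so the stages point in opposite directions and the hypothesis stays open.

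Other divisions of the libraries were counted for each comparison of 3 against 3 libraries, and 10 are too few for a share under 0.05. For genes the real counts were 2958, 5687, 7529 and 9563 for the knockout before and after differentiation, control differentiation and knockout differentiation, and the highest other count was 0 in each by the same edgeR test. For lists the real counts were 17, 18, 9 and 18, and the highest others 13, 12, 7 and 13. In each case 1 division, the real one, gave a count as large. For genes shared between the knockout effects at the 2 stages, 1 of the 100 divisions drawn of 200 possible, the real one, reached 1797. The highest other drawn was 0. That count of 0 follows from the counts of 0 above, so it excludes no chance division and adds nothing for either stage alone.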
